A study of Mus musculus with 12 samples.

How the data were processed

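Total RNA of primary mouse keratinocytes was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample and 12 in all. The deposited values were used as they stood. They are log2 expression values made by the authors with RMA (background correction, quantile normalization and summary of the probes of each transcript cluster), per the submitters' processing notes. The version of RMA is not given in the sources used here, nor whether the 12 arrays went through 1 run. Array medians of 6.77 to 6.84 log2 units are close to one another. No scanner files were used here.

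Groups were taken from the sample titles and sources: wild-type control, wild-type transduced with v-rasHa, MT-HGF control, and MT-HGF mock transduced and treated with AG1478, each with 3 arrays. The series' design text names 3 conditions, while the sample labels give 4, and the labels were followed. For the first 9 arrays the labels carry a shared note on a transduction of 3 days, so how the wild-type and MT-HGF controls were handled in that step is not given in the sources used here. For the AG1478-treated arrays, per the labels' protocols, cells were kept in 8% serum and treated for 24 h, and extraction and labelling are described in other words. No vehicle-treated array of that submission was used here.

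The deposited file held 35511 transcript clusters. The platform's annotation gave 21789 of them a single gene symbol and 1621 several, and 12101 were not listed in it. Of the single-symbol clusters 21698 were matched to current gene records by Entrez ID, which changed 0 symbols. A cluster was kept if its value lay above its array's 30th percentile on at least 3 of the 12 arrays, which kept 25860. Clusters with several symbols or none were left out of the gene tests. A gene with several kept clusters (815 genes) was represented by the cluster with the highest mean, and 15868 genes were tested. Of the genes ranked by the rule for names given further on, Bnip3, Etv5, Idi1, P2rx3 and Pdia4 had 2 kept clusters, which had the same direction in each comparison that ranked them. The clusters of P2rx3 differed in size after AG1478, at -1.59 and -0.07 log2 units. No genome build or coordinates are used. Areg, Hras, Cdkn1a, Isg15, Flg and Gapdh were not analysed here, because they were not among the single-symbol genes that passed the filter.

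A group-means model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8), with default eBayes settings, 8 residual degrees of freedom and 8.02 prior degrees of freedom. The 5 comparisons were RAS with wild type, MT-HGF with wild type, MT-HGF with RAS, AG1478-treated with untreated MT-HGF, and AG1478-treated MT-HGF with wild type. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Fold changes are differences of group means on the log2 scale, with the standard error of limma's moderated fit. Values near the background understate fold changes. Each array's own 95th percentile of the chemosensory receptor genes served as its background. Where a named gene lay at or below it on all 3 arrays of the lower group, its difference is given as a bound. The bound is the mean of the higher group against the mean of these 3 percentiles. Where neither group lay above the background, no difference is given. Among the genes ranked by size a bound applied to 9 of 12 rises and 1 of 12 falls for RAS with wild type, 7 and 3 for MT-HGF with wild type, 1 and 3 for MT-HGF with RAS, 3 and 3 for the AG1478 effect, and 7 and 2 for AG1478 with wild type. The differences of such genes have no settled order. Arrays have no read depth, and their number per group limits the precision.

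The 27 gene lists held 705 names, of which 649 were measured. They cover EGFR ligands, EGFR family receptors and their regulators, EGFR ligand shedding, the HGF and MET pathway, ERK response and feedback, basal layer, spinous, and granular and cornified genes, small proline-rich and stress-type cornified genes, simple epithelial keratins, hair follicle and sebaceous genes, inflammatory cytokines and chemokines, proteases and invasion, cell cycle, p53 and senescence, interferon response, TGF-beta response and mesenchymal transition, hypoxia and glycolysis, cholesterol synthesis, NRF2 and glutathione, unfolded protein and amino acid stress, and metallothionein and zinc response. Others hold markers of melanocytes, fibroblasts, leukocytes and endothelial cells, and chemosensory receptors as a background control. Some genes stand in more than 1 list, such as Dusp6, Plau, Itgb4, Lox and Sesn2. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 27 lists of a comparison. Camera compares a list with all other genes, and a list is said to be called on its adjusted p alone. It was repeated with an estimated correlation, and fry, which tests whether a list's genes move on balance one way without setting them against other genes, was run beside it. The median, the mean and the camera direction had the same sign in all called lists. They differed in sign among lists that were not called: 3 for RAS with wild type, 2 for MT-HGF with wild type, 4 for MT-HGF with RAS, 3 for the AG1478 effect and 3 for AG1478 with wild type.

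The groups, comparisons, tests, filter, lists, alternatives and the rule for named genes were fixed before the data were examined, with some exceptions. These were the test of the HGF and MET list without Hgf, the bounds against the background, and the tests said further on to have been chosen after results were seen. By the rule for named genes the text names, per comparison, up to 12 genes with the largest rise and up to 12 with the largest fall. The text takes these from called genes whose arrays did not overlap between the groups, leaving out predicted genes, non-coding RNAs and chemosensory receptors. It also names up to 4 members of a list with the smallest adjusted p, any other list member, and Hgf, Met, Egfr, the EGFR ligands, Mt1 and Mt2. Genes and families outside the rule are said to have been chosen after their values were seen.

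Overlaps between comparisons that share arrays were set against 100 simulations of unchanged groups and against the count for independent lists. Other splits of the 6 arrays of each comparison (10 per comparison) were refitted. Alternatives were no filter and a stricter filter, the replicate number as a block, eBayes with trend and robust settings, a second quantile normalization, median centring, the mean of a gene's clusters, only the groups compared, array weights, only the first 9 arrays, a log2 fold change of at least 1, and each array left out in turn. The fit was tested on simulated data with 15868 genes, of which 200 were changed. At a log2 change of 0.5 it found 98.75% of changed genes for RAS with wild type, 100% for MT-HGF with wild type, 98.75% for MT-HGF with RAS, 100% for the AG1478 effect and 97.5% for AG1478 with wild type. The false calls in the same order were 3, 7, 13, 11 and 14.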

Results

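Gene expression was measured on 12 microarrays of primary keratinocytes, the main cell type of the epidermis, cultured from FVB/N mice. The arrays fell into 4 groups of 3. Wild-type keratinocytes were the control, and a second set of wild-type cells had been transduced with v-rasHa, a viral oncogenic form of the small GTPase Hras (RAS cells). The third group came from MT-HGF mice, which carry a transgene for hepatocyte growth factor (HGF), the ligand of the receptor tyrosine kinase MET. The fourth group consisted of MT-HGF cells that were mock transduced and treated for 24 h with AG1478. This compound inhibits the tyrosine kinase of the epidermal growth factor receptor (EGFR).

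After the filter on low values, 15868 genes were tested. Array medians lay between 6.77 and 6.84 log2 units, and the mean correlation of an array with the others of its group lay between 0.993 and 0.997. The first principal component held 54.1% of the variance and placed the wild-type arrays at -39.3 to -38.0 and the other 9 at 2.90 to 20.3. On the second component, with 25.5%, the RAS arrays lay at -26.1 to -20.9 and the AG1478-treated arrays at 17.9 to 24.7. As a measure of background, the 153 chemosensory receptor genes that passed the filter, a class taken here as mostly silent in these cells although single members can be expressed in skin, had a 95th percentile between 6.96 and 7.08 log2 units in the 4 groups. Bounds use each array's own percentile, which can differ from these group values. Where a gene was not above it on any array of the lower group, its log2 difference is given as a bound. Such a bound is taken against the mean of these arrays' percentiles and is written as "or higher" or "or lower". The number of arrays, 3 per group, limits the precision of each value. The labels call the replicates of the first 3 groups biological but do not say whether any came from separate animals or cultures, so p-values measure the spread between these arrays, which may be technical.

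The comparison of RAS cells with wild-type cells addressed what oncogenic RAS changes in keratinocytes. Whether the wild-type controls were mock transduced is not given in the sources used here. The oncogene and the transduction step thus cannot be told apart. Genes of the cornified envelope, the protein shell of the outermost epidermal cells, were among the largest rises. Lce3a was higher by 4.91 ± 0.17 log2 units before the bound (SE, n = 3 arrays per group; at least 16-fold; limma adjusted p = 7.18e-13), and Lce3f (3.44 or higher) and Lce3e (4.76) were also higher. The antimicrobial peptide gene Defb14 rose at least 13.6-fold and the keratin gene Krt23 at least 8.79-fold. These folds are bounds against the array background, because Lce3a, Lce3f, Defb14 and Krt23 were not above it in wild-type cells, as held for 9 of the 12 largest rises, whose log2 differences have no settled order. The steepest fall was that of Sostdc1, a secreted antagonist of BMP and Wnt signalling, which was 10.6-fold lower (-3.41 ± 0.16 log2 units). In all, 2004 genes were higher and 3154 lower in RAS cells, 410 and 101 of them by at least 2-fold.

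Other large rises in RAS cells were those of Prl7b1, a member of the placental prolactin family (1.91 or higher), the surface antigen gene Psca (3.41 or higher), the carbonic anhydrase gene Car2 (2.71 or higher), the chemokine gene Ppbp (3.92), the serine protease gene Prss22 (3.84), the retinol dehydrogenase gene Dhrs9 (2.64 or higher) and Acp7 (2.58 or higher). Among the falls were genes of the extracellular matrix and its enzymes, with Ccdc80 at -2.66, the lysyl oxidase gene Lox at -2.56, the collagen receptor gene Itga11 at -2.10 and the protease gene Adamts5 at -1.40 or lower, in log2 units. The smooth muscle actin gene Actg2 (-2.05), Cyp4a12b (-2.44), Lrrc17 (-2.21), Gadd45g (-1.98) and the growth factor genes Tgfb3 (-1.97) and Pdgfc (-1.91) also fell, as did Ccn4 (-1.89). Members of the Lce, Sprr2, Prl, Krt6 and Cyp4a12 families are close in sequence, so probes may be shared and single members are uncertain.

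The ligands of EGFR rose as a group in RAS cells. Of 6 measured, 4 were higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 6.53e-06). Hbegf rose by 2.63 ± 0.13, Tgfa by 2.17 ± 0.076, Btc by at least 1.11 and Ereg by 1.27 ± 0.11 log2 units. Epgn was at 0.11, and Egf was not above background in either group. Transcripts that respond to the ERK kinases rose as well, with 22 of 31 measured members higher and 4 lower (25 and 4 adjusted over the list alone) and adjusted p = 4.79e-13. They included the ERK phosphatase genes Dusp5 (2.12), Dusp4 (1.82) and Dusp6 (1.24) and the transcription factor genes Fos (1.32) and Egr3 (1.24), while Myc fell by 0.27. EGFR family receptors and their regulators had 5 of 12 measured members higher and 4 lower (5 and 4 adjusted over the list alone) and gave no call (adjusted p = 0.31). Egfr was at -0.36, Lrig3 at -0.85 and the feedback inhibitor gene Errfi1 at 0.78. The genes of ligand shedding had 2 of 12 higher and 3 lower (2 and 3 adjusted over the list alone) (adjusted p = 0.928), with the metalloprotease inhibitor gene Timp3 at -1.25 and the protease gene Adam8 at 0.74. The HGF and MET list had 4 of 16 higher and 2 lower (5 and 3 adjusted over the list alone) (adjusted p = 0.123). Met was at 0.36. Hgf was not above background in either group.

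Differentiation genes were grouped by epidermal layer, and differences between the layers were not tested. Granular and cornified genes had 34 of 35 measured members higher and 0 lower (34 and 0 adjusted over the list alone) (adjusted p = 4.11e-43), among them the lipoxygenase gene Alox12b (3.06), Lor, which encodes loricrin (1.90), and the transglutaminase gene Tgm3 (1.91). Small proline-rich and stress-type cornified genes had 15 of 19 higher and 0 lower (16 and 0 adjusted over the list alone) (adjusted p = 9.95e-17). Sprr2g was at 3.48 and S100a8 at 2.74. Spinous genes split: 9 of 19 were higher and 4 lower (9 and 5 adjusted over the list alone). Krt1 (-1.34) and Krt10 (-1.64), the keratin pair of the spinous layer, fell, and the desmosomal gene Dsc2 rose by 2.54. The spinous list was called upward at adjusted p = 0.0107 (adjusted p = 0.179 with an estimated correlation). Simple epithelial keratins had 4 of 5 higher and 0 lower (5 and 0 adjusted over the list alone) (adjusted p = 4.16e-05; adjusted p = 0.0904 with an estimated correlation). Krt18 was at 1.54. Neither the basal layer list, with 5 of 18 higher and 4 lower (6 and 6 adjusted over the list alone) (adjusted p = 0.31), nor the hair follicle and sebaceous list, with 6 of 18 higher and 4 lower (6 and 4 adjusted over the list alone) (adjusted p = 0.284), was called. The hair follicle genes Lgr5 (-0.69 or lower) and Hoxc13 (-1.36) fell.

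Inflammatory cytokine and chemokine genes had 20 of 31 measured members higher and 4 lower (22 and 4 adjusted over the list alone) in RAS cells (adjusted p = 2.92e-08; adjusted p = 0.0635 with an estimated correlation), among them Il24 (3.53), Il1f6 (1.91 or higher) and Il1a (2.17), while Csf1 fell by 0.86. Proteases and invasion genes had 11 of 22 higher and 7 lower (11 and 7 adjusted over the list alone) (adjusted p = 0.0013; adjusted p = 0.201 with an estimated correlation), with the matrix metalloprotease genes Mmp3 at 2.24 or higher, Mmp10 at 2.76 or higher and Mmp13 at 0.74 or higher. Cell cycle genes had 19 of 39 higher and 0 lower (20 and 0 adjusted over the list alone) (adjusted p = 2.57e-06; adjusted p = 0.161 with an estimated correlation). Top2a was at 0.49 and Bub1 at 0.37. Cholesterol synthesis genes had 17 of 19 higher and 0 lower (17 and 0 adjusted over the list alone) (adjusted p = 1.47e-14). Msmo1 was at 1.42 and Cyp51 at 1.15. The unfolded protein and amino acid stress list had 11 of 22 higher and 3 lower (13 and 4 adjusted over the list alone) (adjusted p = 0.00165; adjusted p = 0.0635 with an estimated correlation). Creld2 was at 0.69 and Trib3 at -0.70. Interferon response genes were called downward with 1 of 21 higher and 9 lower (1 and 12 adjusted over the list alone) (adjusted p = 0.00913; adjusted p = 0.0943 with an estimated correlation), Tap1 among them (-0.72). The p53 and senescence list (5 of 17 higher and 7 lower (5 and 9 adjusted over the list alone); adjusted p = 0.512) and hypoxia and glycolysis genes (5 of 20 higher and 2 lower (5 and 2 adjusted over the list alone); adjusted p = 0.0701) gave no call. Neither did NRF2 and glutathione (7 of 21 higher and 8 lower (7 and 8 adjusted over the list alone); adjusted p = 0.698) or metallothionein genes (0 of 6 higher and 1 lower (0 and 1 adjusted over the list alone); adjusted p = 0.772).

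Genes of the TGF-beta response and mesenchymal transition fell in RAS cells, with 2 of 26 measured members higher and 19 lower (3 and 20 adjusted over the list alone) (adjusted p = 1.24e-07), among them Ccn2 (-1.31), Tgfbi (-1.31) and the fibronectin gene Fn1 (-0.92). Fibroblast markers moved with them: 1 of 19 was higher and 12 lower (2 and 13 adjusted over the list alone; adjusted p = 4.82e-07). Col1a1 was at -1.37, Thy1 at -1.21 and Pdgfrb at -1.07. Melanocyte markers (1 of 18 higher and 2 lower (1 and 2 adjusted over the list alone); adjusted p = 0.511) and leukocyte markers (2 of 13 higher and 5 lower (2 and 5 adjusted over the list alone); adjusted p = 0.43) gave no call. The same held for endothelial markers (1 of 11 higher and 2 lower (1 and 2 adjusted over the list alone); adjusted p = 0.715) and the chemosensory control genes (1 of 153 higher and 0 lower (0 and 0 adjusted over the list alone); adjusted p = 0.597). In the RAS comparison 7 of the 14 called lists held with an estimated correlation. The arrays of RAS and wild-type cells did not overlap for 5018 of the 5158 called genes, and for 42.9% of all genes tested, where chance gives 10%. With array weights 3100 genes were higher and 4996 lower.

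The comparison of MT-HGF with wild-type cells addressed the effect of HGF overproduction. Hgf itself was at least 13.2-fold higher (5.76 ± 0.095 log2 units before the bound; SE, n = 3 arrays per group; limma adjusted p = 3.45e-16), from a wild-type mean of 4.91, below the array background, to 10.68. Lce3e and Defb14 rose here too, by 4.35 ± 0.17 and at least 3.34 log2 units. Krt1 fell 15.5-fold (-3.96 ± 0.13) and Krt10 by 3.31 log2 units. Igfbp2, which encodes an insulin-like growth factor binding protein (-4.39), and Sostdc1 (-3.89 or lower) were also lower. MT-HGF cells had 2707 genes higher and 3789 lower than wild type, 491 and 189 by at least 2-fold.

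Further large rises in MT-HGF cells were those of the potassium channel gene Kcnn4 (3.78 or higher), Sprr2g (4.09), Krt23 (3.20 or higher), the serine protease genes Tmprss11e (3.13 or higher) and Prss22 (3.86), Lce3f (2.92 or higher) and Bcl2l15 (2.29 or higher). Large falls were those of Cyp4a12b (-2.51 or lower), Ccdc80 (-3.36), Actg2 (-3.25), Lox (-2.85), Tgfb3 (-2.67), Adamts5 (-1.47 or lower), Adamts1 (-2.43) and the myosin light chain gene Myl9 (-2.43).

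EGFR ligands were higher in MT-HGF cells for 5 of 6 measured and lower for 0 (5 and 0 adjusted over the list alone; adjusted p = 2.40e-05). Tgfa rose by 2.31 ± 0.076, Hbegf by 2.25 ± 0.13, Ereg by 1.71 ± 0.11, Btc by at least 0.96 and Epgn by 0.25 ± 0.063 log2 units. ERK response genes had 21 of 31 measured members higher and 4 lower (21 and 4 adjusted over the list alone) (adjusted p = 1.87e-06). Fos was at 1.67, Dusp5 at 1.59 and Etv5 at 0.93, against Spry4 at -0.47. The HGF and MET list, which holds the transgene Hgf itself, had 7 of 16 higher and 1 lower (8 and 1 adjusted over the list alone) (adjusted p = 0.00178; adjusted p = 0.0696 with an estimated correlation). Without Hgf it had 6 of 15 higher and 1 lower (7 and 1 adjusted over the list alone) (adjusted p = 0.0132; adjusted p = 0.168 with an estimated correlation). Met was at 0.35. Receptors and their regulators had 6 of 12 higher and 3 lower (6 and 3 adjusted over the list alone) (adjusted p = 0.244). Egfr was at -0.40, Erbb3 at 0.57 and Lrig1 at 0.96. Ligand shedding genes had 5 of 12 higher and 3 lower (6 and 3 adjusted over the list alone) (adjusted p = 0.249). Timp3 was at -2.27 and Adam17, which encodes a sheddase of EGFR ligands, at 0.61. Metallothionein genes had 1 of 6 higher and 1 lower (1 and 1 adjusted over the list alone) (adjusted p = 0.874). Mt2 was at 0.25 and Mt1 at 0.10.

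**Figure D1:**
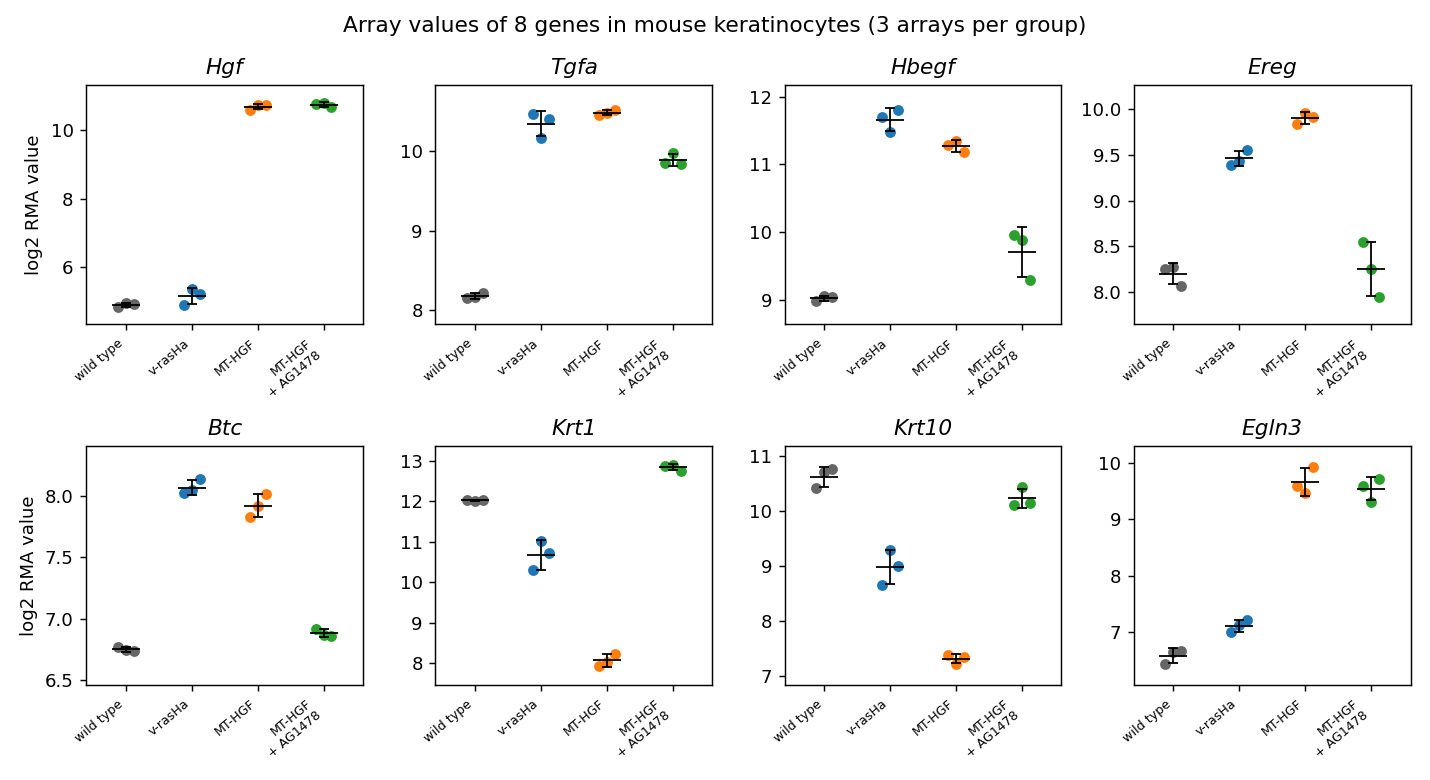
Log2 RMA expression of 8 genes on each of the 12 arrays (dots), with the group mean and SD over 3 arrays, for wild-type, RAS, MT-HGF and AG1478-treated MT-HGF cells. The mean of Hgf is 4.91 in wild-type and 10.68 in MT-HGF cells, and Krt1 fell by 3.96 log2 units in MT-HGF relative to wild-type cells and is higher by 4.78 after AG1478.

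Granular and cornified genes had 33 of 35 measured members higher and 0 lower (33 and 0 adjusted over the list alone) in MT-HGF cells (adjusted p = 9.87e-25). Alox12b was at 2.68, and small proline-rich and stress-type genes had 15 of 19 higher and 1 lower (15 and 2 adjusted over the list alone) (adjusted p = 3.40e-13). S100a8 was at 3.07. The 5 simple epithelial keratins measured were all higher (5 and 0 adjusted over the list alone; adjusted p = 1.08e-06), Krt18 by 2.32 and Krt8 by 1.37. Spinous genes had 9 of 19 higher and 4 lower (10 and 4 adjusted over the list alone), called upward at adjusted p = 0.0105 (adjusted p = 0.168 with an estimated correlation) although Krt1 and Krt10 fell. Basal layer (7 of 18 higher and 3 lower (8 and 3 adjusted over the list alone); adjusted p = 0.15) and hair follicle genes (6 of 18 higher and 4 lower (7 and 4 adjusted over the list alone); adjusted p = 0.244) gave no call. Inflammatory genes had 23 of 31 higher and 3 lower (23 and 3 adjusted over the list alone) (adjusted p = 1.22e-11), among them Il1f6 (3.07 or higher), the neutrophil chemokine gene Cxcl5 (2.02 or higher) and Il24 (3.00). Proteases and invasion genes had 14 of 22 higher and 7 lower (14 and 7 adjusted over the list alone) (adjusted p = 0.0044; adjusted p = 0.257 with an estimated correlation). Hmga2 was at 1.82 and Mmp3 at 0.26 or higher.

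Cell cycle genes had 30 of 39 measured members higher and 0 lower (30 and 0 adjusted over the list alone) in MT-HGF cells (adjusted p = 2.43e-11). Bub1 was at 0.92 and Top2a at 0.87. All 19 measured genes of cholesterol synthesis were higher (19 and 0 adjusted over the list alone; adjusted p = 1.09e-19), Msmo1 by 2.01 and Idi1 by 1.73. Hypoxia and glycolysis genes had 17 of 20 higher and 1 lower (18 and 1 adjusted over the list alone) (adjusted p = 8.97e-10). Egln3, a prolyl hydroxylase gene induced by low oxygen, was at 2.70 or higher and Bnip3 at 1.43. The unfolded protein and amino acid stress list had 18 of 22 higher and 0 lower (18 and 0 adjusted over the list alone) (adjusted p = 3.54e-10). Creld2 was at 1.34 and Chac1 at 1.06. The p53 (3 of 17 higher and 8 lower (3 and 9 adjusted over the list alone); adjusted p = 0.142) and interferon lists (2 of 21 higher and 8 lower (2 and 8 adjusted over the list alone); adjusted p = 0.249) gave no call. NRF2 genes gave none either (8 of 21 higher and 6 lower (9 and 6 adjusted over the list alone); adjusted p = 0.2).

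TGF-beta response and mesenchymal genes fell in MT-HGF cells, with 2 of 26 measured members higher and 19 lower (2 and 19 adjusted over the list alone) (adjusted p = 5.40e-08), Ccn2 at -1.78 and Id2 at -1.49. Fibroblast markers moved both ways, with 5 of 19 higher and 13 lower (5 and 13 adjusted over the list alone) (adjusted p = 0.0234, downward; adjusted p = 0.0794 with an estimated correlation). Thy1 was at -1.16 and Col1a1 at -0.72, while the proteoglycan gene Dcn rose by 1.77 and Fbln1 by 0.90. Melanocyte markers had 1 of 18 higher and 11 lower (1 and 11 adjusted over the list alone) (adjusted p = 0.00955, downward; adjusted p = 0.421 with an estimated correlation). Mlana was at -0.79, Pmel at -0.47 and Tyrp1 at -0.33. Leukocyte (2 of 13 higher and 6 lower (2 and 7 adjusted over the list alone); adjusted p = 0.111) and endothelial markers (2 of 11 higher and 2 lower (2 and 2 adjusted over the list alone); adjusted p = 0.616) gave no call. Chemosensory genes gave none (1 of 153 higher and 7 lower (0 and 0 adjusted over the list alone); adjusted p = 0.119). The chemosensory median change was -0.083 log2 units, so a background shift may enter small falls, and 3600 of the 3789 falls were under 2-fold. With an estimated correlation 11 of the 16 called lists held. Arrays of the MT-HGF and wild-type groups did not overlap for 6323 of the 6496 called genes, and for 50.4% of all genes, against 10% by chance.

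Many genes were called in the same direction in RAS and MT-HGF cells relative to wild type. Both raised 1570 genes, where independent lists of these sizes would share 342, and both lowered 2171, where 753 would be shared. Opposite directions were found for 111 genes. Examples raised in both were Hbegf, Tgfa, Krt23 and Defb14, and lowered in both were Sostdc1, Lox and Krt10. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.825. Because both comparisons use the same 3 wild-type arrays, unchanged groups simulated against them gave r = 0.499 by chance. The covariance was 0.160 against a simulated 0.00353. Part of the excess may come from the shared controls, since 3 arrays cannot be split into 2 sets of 2.

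**Figure D2:**
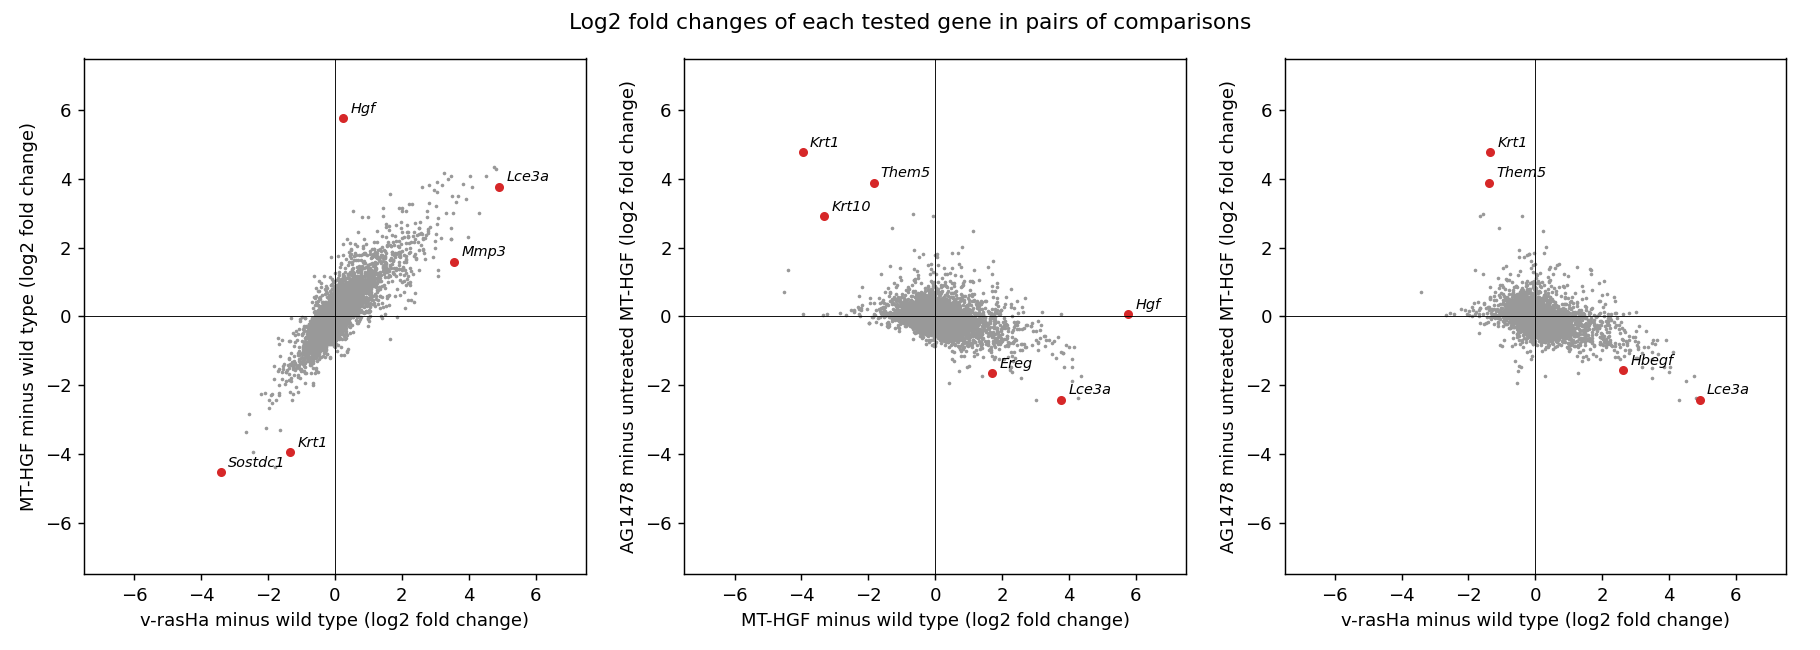
Log2 fold changes of all 15868 tested genes (dots) in RAS against MT-HGF cells, each relative to wild type (left), in MT-HGF cells against the AG1478 comparison (middle), and in RAS cells against the AG1478 comparison (right), with named genes in red. The left panel has r = 0.825, the middle r = -0.366 and the right r = -0.388, and only the right pair shares no arrays.

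The direct comparison of MT-HGF with RAS cells addressed where their profiles differ. The RAS cells were transduced, while how the MT-HGF controls were handled in that step is not given in the sources used here. Differences between HGF and RAS thus cannot be told apart from those of the transduction step. After Hgf (3.70 or higher), the largest rise in MT-HGF cells was that of Egln3, which was 5.84-fold higher (2.55 ± 0.12 log2 units; SE, n = 3 arrays per group), followed by Sncg (2.09), Cxcl5 (1.91), Nt5dc2 (1.90), the mucin gene Muc15 (1.90) and the lactate transporter gene Slc16a3 (1.85). Krt1 was 6.12-fold lower than in RAS cells (-2.61 ± 0.13), and Igfbp2 (-2.58), Serpinb12 (-0.76 or lower), Mmp3 (-1.98) and Mmp10 (-1.73) were also lower. Of all genes, 2129 were higher in MT-HGF cells and 2002 lower, 89 and 70 by at least 2-fold. Which direction held more genes was not settled, since median centring gave 2063 and 2097. Tgfa was at 0.14 and Btc at -0.15, neither called, whereas Ereg (0.44) was higher and Hbegf (-0.39) lower in MT-HGF cells.

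Groups that were higher in MT-HGF than in RAS cells were cholesterol synthesis (17 of 19 higher and 0 lower (17 and 0 adjusted over the list alone); adjusted p = 6.32e-15) and the unfolded protein and amino acid stress list (14 of 22 higher and 1 lower (16 and 1 adjusted over the list alone); adjusted p = 1.01e-08). Fibroblast markers were higher too (12 of 19 higher and 3 lower (12 and 3 adjusted over the list alone); adjusted p = 2.05e-05). Dcn was at 1.69. Hypoxia and glycolysis genes had 13 of 20 higher and 2 lower (17 and 3 adjusted over the list alone) (adjusted p = 1.01e-08; adjusted p = 0.0589 with an estimated correlation). Pdk1 was at 1.29, Bnip3 at 1.28 and the glucose transporter gene Slc2a1 at 0.66, against Hk2 at -1.01. Inflammatory genes had 20 of 31 higher and 3 lower (20 and 3 adjusted over the list alone) (adjusted p = 7.47e-07; adjusted p = 0.167 with an estimated correlation). Il33 was at 1.45. Cell cycle genes had 19 of 39 higher and 0 lower (22 and 0 adjusted over the list alone) (adjusted p = 3.61e-06; adjusted p = 0.243 with an estimated correlation). Simple keratins had 4 of 5 higher and 0 lower (4 and 0 adjusted over the list alone) (adjusted p = 4.71e-04; adjusted p = 0.243 with an estimated correlation). The HGF and MET list had 6 of 16 higher and 1 lower (7 and 3 adjusted over the list alone) (adjusted p = 0.0138; adjusted p = 0.243 with an estimated correlation). Without Hgf it was not called (5 of 15 higher and 1 lower (6 and 3 adjusted over the list alone); adjusted p = 0.107).

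Granular and cornified genes were lower in MT-HGF than in RAS cells, with 6 of 35 higher and 20 lower (6 and 21 adjusted over the list alone) (adjusted p = 2.16e-07; adjusted p = 0.322 with an estimated correlation), among them Lce1b (-1.79) and Rptn (-1.02). ERK response genes had 4 of 31 higher and 12 lower (4 and 12 adjusted over the list alone) (adjusted p = 0.024; adjusted p = 0.32 with an estimated correlation). Spry4 was at -0.80 and Dusp4 at -0.65. TGF-beta response genes had 3 of 26 higher and 9 lower (4 and 12 adjusted over the list alone) (adjusted p = 0.0184; adjusted p = 0.276 with an estimated correlation). Melanocyte markers had 1 of 18 higher and 11 lower (1 and 13 adjusted over the list alone) (adjusted p = 4.61e-05; adjusted p = 0.317 with an estimated correlation). The chemosensory control genes were also called downward, with 1 of 153 higher and 4 lower (0 and 0 adjusted over the list alone) (adjusted p = 0.00934; adjusted p = 0.755 with an estimated correlation), so small shifts at the preset correlation are not specific here. Only 3 of the 13 called lists held with an estimated correlation. Of all genes, 39.2% had arrays that did not overlap between the groups, against 10% by chance.

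The comparison of AG1478-treated with untreated MT-HGF cells addressed the part of the MT-HGF profile that depends on EGFR activity. Krt1 was 27.4-fold higher in treated cells (4.78 ± 0.13 log2 units; SE, n = 3 arrays per group; limma adjusted p = 5.20e-13) and Krt10 7.54-fold higher (2.92 ± 0.13). Them5, an acyl-CoA thioesterase gene, rose 14.8-fold. EGFR ligand transcripts fell: Ereg was 3.15-fold lower (-1.66 ± 0.11) and Hbegf 2.96-fold lower (-1.57 ± 0.13). In all, 1043 genes were higher and 1572 lower, 58 and 47 by at least 2-fold. The treated arrays were submitted later with other notes on growth, RNA extraction and labelling. The treated cells were mock transduced, while the handling of the untreated MT-HGF cells in that step is not given in the sources used here. No untreated array of the later submission was used here, so treatment cannot be told apart from batch or from transduction handling.

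Other genes that rose after AG1478 were Dapl1 (2.98), Clca3a2 (1.68 or higher), Pou2f3, a transcription factor gene of differentiating epidermis (2.16 or higher), Chil1 (2.47), the aldehyde oxidase gene Aox4 (2.01), the cytokine gene Il18 (1.94), the kallikrein protease gene Klk14 (1.86) and Gsdmc (1.33 or higher). Lce3a (-2.42), Prl7b1 (-0.49 or lower), the cationic amino acid transporter gene Slc7a3 (-1.93), Defb14 (-1.88), Cth, which encodes cystathionine gamma-lyase (-1.73), Car2 (-0.91 or lower) and the ATP receptor gene P2rx3 (-0.96 or lower; its other cluster was at -0.07) fell. Hgf was at 0.06.

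Of 6 EGFR ligands, 5 were lower and 0 higher after AG1478 (0 and 5 adjusted over the list alone; adjusted p = 2.73e-08), including Btc (-0.84 or lower), Epgn (-0.71) and Tgfa (-0.60). ERK response genes had 2 of 31 measured members higher and 19 lower (2 and 22 adjusted over the list alone) (adjusted p = 8.88e-12). Dusp4 was at -1.15, Dusp6 at -1.14, Fos at -1.04 and Etv5 at -1.02. The unfolded protein and amino acid stress list had 0 of 22 higher and 13 lower (0 and 15 adjusted over the list alone) (adjusted p = 4.71e-10). Trib3 was at -0.87, Chac1 at -0.84 and Psat1 at -0.69. These 3 of 17 called lists held with an estimated correlation. Egfr was at 0.10, while Erbb2 rose by 0.48 and Erbb3 by 0.33, and Met fell by 0.37.

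Spinous genes had 9 of 19 measured members higher and 2 lower (9 and 3 adjusted over the list alone) after AG1478 (adjusted p = 0.00153; adjusted p = 0.17 with an estimated correlation). Calml3 was at 1.38 and Krt77 at 1.30 beside Krt1 and Krt10. Granular and cornified genes were called downward but split, with 7 of 35 higher and 14 lower (7 and 16 adjusted over the list alone) (adjusted p = 0.00915; adjusted p = 0.637 with an estimated correlation). Alox12b was at -0.89 and Ivl, which encodes involucrin, at -0.64, against Rptn at 1.04 and Tgm3 at 0.97. Small proline-rich and stress-type genes had 3 of 19 higher and 10 lower (4 and 11 adjusted over the list alone) (adjusted p = 0.00238; adjusted p = 0.274 with an estimated correlation). Sprr2g was at -1.23 and Sprr2b at 1.48. Hair follicle genes were called upward, with 7 of 18 higher and 3 lower (8 and 3 adjusted over the list alone) (adjusted p = 0.0127; adjusted p = 0.222 with an estimated correlation), Tchh among them (1.54). Simple keratins had 0 of 5 higher and 3 lower (0 and 3 adjusted over the list alone) (adjusted p = 0.0139; adjusted p = 0.274 with an estimated correlation).

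Protease and invasion genes had 2 of 22 measured members higher and 11 lower (2 and 11 adjusted over the list alone) after AG1478 (adjusted p = 2.49e-05; adjusted p = 0.17 with an estimated correlation). Mmp10 was at -0.94, Plaur at -0.88 and Itga3, a basal layer integrin gene, at -0.56. Inflammatory genes had 4 of 31 higher and 11 lower (5 and 13 adjusted over the list alone) (adjusted p = 0.00526; adjusted p = 0.274 with an estimated correlation). Tslp was at -0.88 and Vegfa at -0.76, against Lcn2 at 1.43. Cell cycle genes had 0 of 39 higher and 12 lower (0 and 16 adjusted over the list alone) (adjusted p = 7.38e-06; adjusted p = 0.222 with an estimated correlation). Bub1 was at -0.41 and Ccnd1, which encodes cyclin D1 and is in the ERK list, at -0.41. Cholesterol synthesis had 1 of 19 higher and 10 lower (1 and 15 adjusted over the list alone) (adjusted p = 7.38e-06; adjusted p = 0.17 with an estimated correlation). Msmo1 was at -0.52. Hypoxia and glycolysis had 0 of 20 higher and 4 lower (0 and 4 adjusted over the list alone) (adjusted p = 0.0119; adjusted p = 0.274 with an estimated correlation). The HGF and MET list had 1 of 16 higher and 7 lower (2 and 7 adjusted over the list alone) (adjusted p = 0.038; adjusted p = 0.255 with an estimated correlation). Interferon genes were called upward (2 of 21 higher and 1 lower (4 and 1 adjusted over the list alone); adjusted p = 0.0124; adjusted p = 0.17 with an estimated correlation). So were p53 genes (5 of 17 higher and 1 lower (6 and 2 adjusted over the list alone); adjusted p = 0.0472; adjusted p = 0.246 with an estimated correlation).

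Markers of other cell types gave no call after AG1478: fibroblast markers had 0 of 19 higher and 1 lower (0 and 0 adjusted over the list alone) (adjusted p = 0.576) and melanocyte markers 1 of 18 higher and 0 lower (0 and 0 adjusted over the list alone) (adjusted p = 0.719). Leukocyte markers had 1 of 13 higher and 0 lower (1 and 0 adjusted over the list alone) (adjusted p = 0.275) and endothelial markers 0 of 11 higher and 1 lower (0 and 1 adjusted over the list alone) (adjusted p = 0.909). The chemosensory control genes were called upward, with 4 of 153 higher and 0 lower (0 and 0 adjusted over the list alone) (adjusted p = 7.10e-05; adjusted p = 0.597 with an estimated correlation), their median moving from 6.06 to 6.16 log2 units. The chemosensory median was 6.16 in wild-type and 6.14 in RAS cells, so the untreated MT-HGF arrays of the first submission had the low values. The chemosensory genes had a median change of 0.096 log2 units. The medians of the interferon (0.12), p53 (0.13), hair follicle (0.13) and spinous lists (0.14) were near it. Small upward shifts of lists at the preset correlation are thus not specific here. Apart from the threshold of 2-fold, the number of higher genes moved by over 1.5 times in the following cases. It was 683 without replicate 2 of the untreated MT-HGF cells and 1795 with array weights. Arrays of the treated and untreated groups did not overlap for 34.2% of all genes, against 10% by chance.

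**Figure D3:**
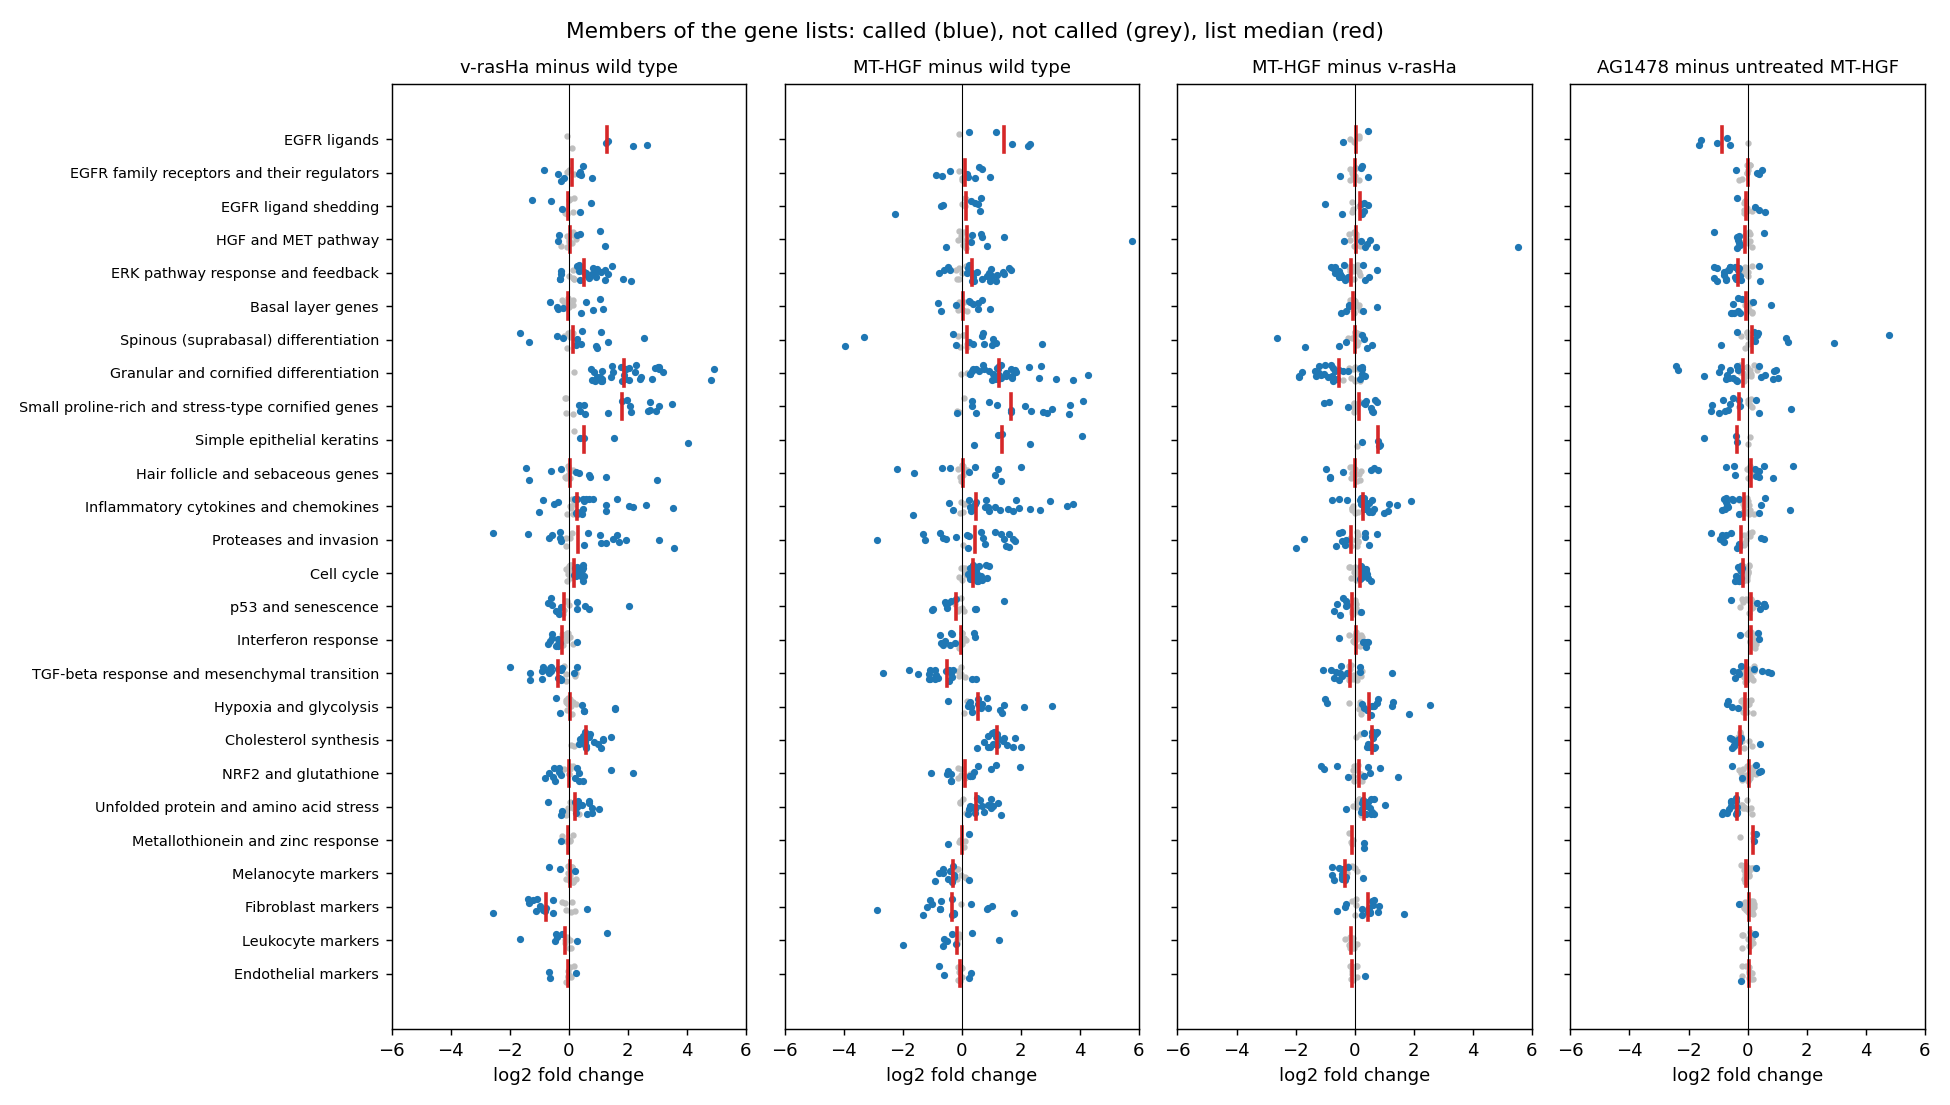
Log2 fold changes (x axis) of the measured members of 26 gene lists in 4 comparisons, with called members in blue, others in grey and the list median in red. All 19 measured cholesterol synthesis genes are higher in MT-HGF than in wild-type cells, and 5 of 6 EGFR ligands and 19 of 31 ERK response genes are lower after AG1478.

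Genes changed in MT-HGF cells were set against the AG1478 comparison. Of the genes higher in MT-HGF than in wild-type cells, 907 were lower after AG1478, where independent lists would share 268, and of those lower in MT-HGF cells 451 were higher after AG1478, where 249 would be shared. Krt1, Krt10, Ereg, Hbegf and Dusp6 were among these 1358 genes, while 411 genes moved further in the same direction. Because both comparisons use the untreated MT-HGF arrays with opposite sign, unchanged groups gave r = -0.500 in simulations, and the observed r was -0.366. The covariance was -0.0414 against a simulated -0.00353, and part of this may come from the shared arrays. With array weights 2053 genes were called in opposite directions.

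The RAS effect and the AG1478 effect share no arrays. They correlated at r = -0.388 across genes, with a covariance of -0.0388. Of 100 combinations of splits of the arrays, 10 gave r as large in size, the real one included, up to 0.550. The other splits mix arrays of the real groups and keep part of the real differences, so this count does not measure chance. The limits on batch given for the AG1478 comparison apply here too. Of the genes higher in RAS than in wild-type cells, 786 were lower after AG1478 in MT-HGF cells, where independent lists would share 199. Of those lower in RAS cells, 497 were higher after AG1478, where 207 would be shared. Among the 410 genes at least 2-fold higher in RAS cells, which include Lce3a, Hbegf and Mmp3, the median AG1478 effect was -0.37 log2 units, and 249 were called lower. Among the 101 genes at least 2-fold lower, which include Krt1 and Krt10, the median was 0.17, and 33 were called higher. In total 1283 genes had opposite directions and 298 the same direction, and with array weights 1996 had opposite directions.

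AG1478-treated MT-HGF cells still differed widely from wild-type cells. Hgf was at least 13.8-fold higher, the interleukin 36 family genes Il1f6 and Il1f8 were higher by at least 3.13 and by 3.33 ± 0.16 log2 units, and Kcnn4 (2.89 or higher), Muc15 (2.60 or higher) and Egln3 (2.58 or higher) were also higher (SE, n = 3 arrays per group). Cyp4a12b (-2.35 or lower), Sostdc1 (-3.83), Ccdc80 (-3.31) and Actg2 (-3.18) were lower. In contrast, Ereg was at 0.05, Met at -0.02 and Dusp4 at 0.02 relative to wild type, none of them called, Btc was not above background in either group, and Tgfa (1.71) and Hbegf (0.68) were still higher. Of the 491 genes at least 2-fold higher in MT-HGF than in wild-type cells, 483 were also called higher in treated cells, and their median difference from wild type was 1.52 without and 1.26 with AG1478. Of the 189 genes at least 2-fold lower, 182 were also called lower, with medians of -1.30 and -1.19. Both comparisons use the same 3 wild-type arrays, and as many genes picked by size from simulated unchanged groups had medians of 0.19 and 0.10 for the rises and -0.23 and -0.12 for the falls, with 431 of 491 and 171 of 189 in the same direction. Part of the agreement may come from the shared controls and the choice by size. In total 2663 genes were higher and 4151 lower than in wild type.

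By list, treated MT-HGF cells showed no call by camera relative to wild type for EGFR ligands (2 of 6 higher and 1 lower (2 and 1 adjusted over the list alone); adjusted p = 0.317) or ERK response genes (8 of 31 higher and 9 lower (8 and 9 adjusted over the list alone); adjusted p = 0.566). By fry, which does not set a list against other genes, EGFR ligands were higher (adjusted p = 1.40e-04) and ERK response genes were not called (adjusted p = 0.0933). Cholesterol synthesis (19 of 19 higher and 0 lower (19 and 0 adjusted over the list alone); adjusted p = 3.37e-16) and spinous genes (13 of 19 higher and 1 lower (14 and 1 adjusted over the list alone); adjusted p = 1.43e-07) were higher. Small proline-rich genes were higher as well (17 of 19 higher and 0 lower (17 and 0 adjusted over the list alone); adjusted p = 2.20e-14), and TGF-beta response genes were lower (0 of 26 higher and 19 lower (0 and 19 adjusted over the list alone); adjusted p = 3.29e-08). Fibroblast markers had 5 of 19 higher and 12 lower (5 and 13 adjusted over the list alone) (adjusted p = 0.0579). Granular and cornified genes were called upward (31 of 35 higher and 0 lower (31 and 1 adjusted over the list alone); adjusted p = 5.45e-20; adjusted p = 0.104 with an estimated correlation). So were inflammatory genes (22 of 31 higher and 3 lower (22 and 3 adjusted over the list alone); adjusted p = 6.33e-09; adjusted p = 0.0869 with an estimated correlation). Hypoxia genes were as well (13 of 20 higher and 1 lower (14 and 1 adjusted over the list alone); adjusted p = 1.89e-06; adjusted p = 0.0914 with an estimated correlation). Other lists called upward were simple keratins (5 of 5 higher and 0 lower (5 and 0 adjusted over the list alone); adjusted p = 8.82e-06; adjusted p = 0.0914 with an estimated correlation) and cell cycle genes (24 of 39 higher and 2 lower (25 and 2 adjusted over the list alone); adjusted p = 2.66e-05; adjusted p = 0.24 with an estimated correlation). So were hair follicle genes (9 of 18 higher and 5 lower (9 and 5 adjusted over the list alone); adjusted p = 0.0339; adjusted p = 0.24 with an estimated correlation) and the unfolded protein and amino acid stress list (13 of 22 higher and 5 lower (13 and 5 adjusted over the list alone); adjusted p = 0.0339; adjusted p = 0.197 with an estimated correlation). Melanocyte markers were called downward (2 of 18 higher and 11 lower (2 and 13 adjusted over the list alone); adjusted p = 0.00672; adjusted p = 0.466 with an estimated correlation). The other lists gave no call by camera. The limits on batch given for the AG1478 comparison apply here too, and with array weights 4367 genes were higher. Arrays did not overlap for 50.5% of all genes, against 10% by chance.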

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

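The tests of the background shift and of the covariance were chosen after the result was seen, the fibroblast tests after the marker calls were seen, and the melanocyte tests after the counts of that list, but not its members' levels, were seen. Clusters without a single gene symbol, which the comparisons of genes leave out, also carried signal above wild type. Of 8562 such clusters that passed the filter, 36 were at least 2-fold higher in RAS than in wild-type cells and 70 were at least 2-fold higher in MT-HGF than in wild-type cells. Groups of 3 arrays were not tested for outlying arrays.

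For each of the 5 comparisons the 6 arrays make 10 splits, too few for a share under 0.05. The real split gave 5158 called genes for RAS with wild type, 6496 for MT-HGF with wild type, 4131 for MT-HGF with RAS, 2615 for the AG1478 effect and 6814 for AG1478 with wild type. The highest count of another split was 0 in each, so 1 of 10 splits gave as many genes. Every other split mixes arrays of both real groups, so real differences widen the fitted spread. A count of 0 there therefore does not measure chance.

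The AG1478 effect is confounded with the later submission. It ran against the RAS effect, with which it shares no arrays (r = -0.388). Of the 100 combinations of splits, 10 gave r as large in size, up to 0.550. The other splits carry part of the real effects, so this count neither measures chance nor decides the question. Array processing of the later arrays stays open. By covariance, 1 of 100 combinations was as large (-0.0388, highest other 0.0173). Covariance grows with the size of both effects. Other splits mix the groups and shrink the effects, so this count cannot decide the question. For the genes that rose, a shift of the array background may account for small changes. The median change of the 153 chemosensory genes that passed the filter was 0.275 of the median size of called changes, rises and falls together. Over all single-symbol chemosensory clusters the shift was smaller, with array medians of 5.14 to 5.17 in untreated and 5.20 to 5.24 in treated cells. The account thus depends on which control genes are taken. For the genes that fell, a background shift stays open. The 60.1% of called genes that moved against the chemosensory rise are the falls themselves and decide nothing. Culture differences between the submissions cannot be told apart from the treatment because 0 untreated arrays with the later notes were used here, and EGFR inhibition itself remains among the open explanations.

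Fibroblast markers were called downward in RAS cells (adjusted p = 0.0144 with an estimated correlation) and in MT-HGF cells, where the call was lost (adjusted p = 0.0794 with an estimated correlation) and 5 of 19 markers were higher. Fewer fibroblasts in the MT-HGF cultures as the whole cause would not raise such markers. Of 15 markers above background 11 were lower but 4 were higher, with Dcn at 1.77 and Fbln1 at 0.90. These rises argue against it as the whole cause. The bounds of this test and of that for RAS cells were set after the calls were seen, so they add no independent support. For RAS cells the same explanation stays open, with 10 of 15 lower, fewer than it needs, and 1 higher. A direct effect of v-rasHa or HGF on these genes is possible and was not tested, and the TGF-beta response list fell in both groups of cells.

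Melanocyte markers were called downward in MT-HGF relative to wild-type cells, with 11 of 18 lower, but the call was lost (adjusted p = 0.421 with an estimated correlation). Drift near background is argued against, since 10 of the 11 markers called lower lay above the 95th percentile of the chemosensory genes in wild-type cells, where Tyrp1 was at 12.47 and Dct at 11.82 log2 units. Fewer melanocytes in the MT-HGF cultures would need falls of the pigment genes, and of Tyr, Tyrp1, Dct, Pmel and Mlana 4 were lower, with Tyr at 0.13 not called. That explanation may hold in part, but the falls of Mlana, Pmel and Tyrp1 given above were unequal in size and Tyr did not fall. Whether fewer melanocytes alone can give such unequal changes was not tested. A change within the melanocytes under HGF, whose receptor they carry, was not tested either.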

How the results depend on the processing

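No called list or named gene reversed its direction. For MT-HGF with RAS, where 2129 genes were higher and 2002 lower, the balance turned with median centring (2063 and 2097), without replicate 1 of the RAS cells (1853 and 1920) and without replicate 3 of the MT-HGF cells (1699 and 1847), and a second quantile normalization gave 2263 each way. In the other 4 comparisons it turned with the threshold of 2-fold. Among all called genes, 1 for MT-HGF with wild type and 1 for AG1478 with wild type were called in the opposite direction with the mean of a gene's clusters. Over all alternatives the call status of single named genes was unchanged in 9893 cases, lost in 351 and gained in 51. For lists it was unchanged in 1382 cases, lost in 67 and gained in 41. Unchanged cases include genes and lists called in neither setting, so they do not count calls that were kept. Of the losses, 269 for genes came with the threshold of 2-fold and 44 for lists with an estimated correlation. The alternatives counted include the HGF and MET list without Hgf, chosen after seeing the data. Its call for MT-HGF with RAS was lost (adjusted p = 0.107).

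Counts moved by over 1.5 times with array weights, whose estimation did not reach its tolerance: 3100 genes were higher and 4996 lower in RAS than in wild-type cells, 1795 were higher after AG1478, 4367 were higher in AG1478-treated than in wild-type cells, 2053 reversed between the MT-HGF and AG1478 effects and 1996 were opposite between the RAS and AG1478 effects. The cause was not tested. A log2 fold change of at least 1 left, by construction, 410 higher and 101 lower genes for RAS with wild type, 491 and 189 for MT-HGF with wild type, 89 and 70 for MT-HGF with RAS, 58 and 47 for the AG1478 effect and 434 and 158 for AG1478 with wild type. With it 396 genes were shared by the RAS and MT-HGF effects, 47 reversed under AG1478 and 44 were opposite between the RAS and AG1478 effects.

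With an estimated inter-gene correlation, 5 lists were higher for RAS with wild type, 1 was lower for MT-HGF with wild type, 3 were higher and 0 lower for MT-HGF with RAS, 0 were higher and 3 lower for the AG1478 effect, and 3 were higher and 1 lower for AG1478 with wild type. With fry 6 lists were lower for MT-HGF with wild type. Leaving out 1 array at a time gave 683 (without replicate 2 of the untreated MT-HGF cells) to 912 genes (without replicate 1) higher after AG1478, and no other count moved by over 1.5 times. Fewer arrays are part of each such fit.

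With the replicate number as a block, 2029 genes were higher and 3233 lower in RAS cells, 2733 and 3825 in MT-HGF cells, 2204 and 2050 for MT-HGF with RAS, 1086 and 1622 for the AG1478 effect, and 2751 and 4208 for AG1478 with wild type. The numbers were not taken as pairs, although the first 9 arrays gave mixed evidence. Same-numbered deviations correlated at 0.0868 to 0.495 between RAS and MT-HGF cells, where 6 of 6 arrays were closest to their own number, and at 0.0465 to 0.528 between wild-type and MT-HGF cells (4 of 6), but at -0.244 to 0.395 between wild-type and RAS cells (3 of 6) and at -0.266 to 0.0517 between MT-HGF cells and treated cells (1 of 6). Signal over background limits genes with low values, as 65.6% to 67.6% of the tested genes lay above the 95th percentile of the chemosensory genes.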

Other observations

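The gene families in this part were chosen after their values were seen. Of 10 contractile genes of smooth muscle and myofibroblasts measured, 9 were lower in RAS and 8 in MT-HGF cells relative to wild type, and none was higher. Actg2 was at -2.05 and -3.25, Myl9 at -1.77 and -2.43, Tagln at -1.49 and -1.97, and Acta2 at -1.05 and -1.78 log2 units in RAS and MT-HGF cells. After AG1478 their median change was 0.11 log2 units with no member called by limma, and Acta2 was at 0.19. Of 19 fibroblast markers, 12 were lower and 1 higher in RAS cells, and 13 were lower and 5 higher in MT-HGF cells, where the list call was lost (adjusted p = 0.0794 with an estimated correlation). Of the placental prolactin family, 5 of 5 genes measured were higher in RAS cells and 4 in MT-HGF cells. Prl8a9 was at 3.48 and 2.57. The means of Prl2a1 and Prl2c1 lay under the array background in all 4 groups, so their calls carry little weight. Prl7b1 passed the low-value filter only through the RAS and untreated MT-HGF arrays. In MT-HGF cells 5 of 5 family members were lower than in RAS cells. After AG1478 3 fell further, Prl7b1 by at least 0.49 and Prl8a9 by 1.81. These genes are close in sequence, so single members are uncertain.

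Genes of amino acid transport and metabolism, with the stress genes Chac1, Trib3 and Ddit3 among them, were counted without a test of the family. Of 21 measured, 17 were higher in MT-HGF than in RAS cells and 0 lower. Relative to wild type, 13 were higher and 1 lower in MT-HGF cells, 3 higher and 9 lower in RAS cells, and 3 higher and 15 lower in AG1478-treated cells. In AG1478-treated relative to untreated MT-HGF cells, where treatment and submission are confounded, 19 were lower and 0 higher, among them Slc7a3 (-1.93), Cth (-1.73), Aldh1l2 (-1.49), Bcat1 (-1.23) and the one-carbon enzyme gene Mthfd2 (-1.16). The exceptions were Cbs (0.19) and the cystine transporter gene Slc7a11 (0.19). The stress genes Chac1 (-0.84), Trib3 (-0.87) and Ddit3 (-0.40) were within the 19. Some of these genes are also in the unfolded protein and amino acid stress list, which was called upward in treated relative to wild-type cells (adjusted p = 0.197 with an estimated correlation). Kallikrein proteases were higher for 10 of 13 measured in RAS and in MT-HGF cells, Klk9 being at 3.50 and 3.51. After AG1478 4 kallikreins were higher and 3 lower, with Klk14 at 1.86. The 3 stefin genes measured, which encode cysteine protease inhibitors, were higher in RAS cells and higher again in MT-HGF than in RAS cells. After AG1478 2 of them rose further, with Stfa3 at 1.05. The means of Cstdc6, counted among the stefins, lay under the array background in wild-type (6.08) and RAS cells (6.67).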
